A study of Mus musculus with 6 samples.

How the data were processed

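Polyadenylated RNA of 6 samples of mouse hepatic stellate cells was measured by sequencing, 3 treated with DMSO and then VIP and 3 with OCA and then VIP. The authors deposited 1 table of exon counts for 24940 genes, each with 1 RefSeq transcript, in the layout that HOMER writes. Per the deposited table, the values are expected counts not adjusted for library size, in steps of 0.5. Its other columns hold the exon length of each transcript and the number of its genomic copies, which is above 1 for 409 genes. The submitters' notes name the mm10 genome, STAR, HOMER and DESeq2, with no role, order or version. Whether counting used strand and whether duplicates were removed are not stated. The columns were assigned to groups by their names; their numbers were not matched to the letters in the sample titles, so libraries are numbered here as the columns are.

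Column totals were 2.84e+06 to 4.57e+06 for DMSO+VIP and 4.53e+06 to 9.95e+06 for OCA+VIP. Low counts come in steps of about 6, so a floor of 3 such steps, 18 counts over the 3 libraries of a group, was used as the level that a count of 0 allows. Folds against a group at 0 are lower bounds against this floor. The floor covers only the counting error of the group at 0, and the count of the other group enters as measured. CPM of genes and lists are counts scaled to the column total, without TMM, while correlations and principal components used log2 CPM scaled to the TMM-normalised library size, and errors are SD over 3 libraries.

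The deposited values were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1). The steps were TMM normalization, filterByExpr by group (minimum count 10, minimum total 15), a quasi-likelihood F test of OCA+VIP against DMSO+VIP and Benjamini-Hochberg adjustment over all tested genes, with a threshold of 0.05. All tests are two-sided. There were 4 residual degrees of freedom and the common biological coefficient of variation was 0.198. For 27 gene lists fixed before the data were examined, members past the threshold were counted, adjusted over all genes and over the list alone. The 26 lists with at least 2 tested genes were compared with the other genes by camera on voom values with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run as alternatives. The symbols Ccn1 and Ccn2 were read as Cyr61 and Ctgf, and Ugt2b4, Muc16, Trac and Trbc2 are not in the table.

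The named genes follow a rule set before the data were examined. It takes 7 genes of the VIP and FXR pathway, the 10 rises and 10 falls of largest size and the 5 rises and 5 falls of smallest p, with a mean of at least 1 CPM and no overlap between groups. It also takes the 4 members of smallest p in each list with a mean of at least 1 CPM. Predicted genes and small RNA genes were left out of the choices by size and p. The rule gave 125 genes, of which 93 passed the test. Other genes are named as chosen after their values were seen. The result of 1 gene is not reported here.

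The alternatives set beforehand were RLE, upper-quartile and library-size scaling, no filter, a filter of 1 CPM in 3 samples, DESeq2 1.42.0, limma-voom, a replicate block in edgeR and in DESeq2, thresholds of 0.01 and 0.1, and leaving out each library and each replicate number. Counts divided by 6, those counts thinned to the smallest such total (OCA+VIP library 2 is less stepped, so this need not equalise fragments), and cyclic loess were chosen after the data were seen. Splits of the 6 libraries into 3 and 3 were refitted. Permutation tests on lists used 100000 permutations of genes, not of libraries. Their p treats genes as independent and does not measure the spread between libraries. The edgeR steps were tested on simulated data with 11272 genes: 67% of 2-fold and 91% of 4-fold changes were recovered, each with the right sign, with 8 false calls. The simulation gave every gene the same dispersion (0.0078) and whole steps of 6 counts, and it changed no gene of low mean CPM. These rates therefore need not hold for the real libraries or for genes of low CPM. Exon overlaps with other genes were taken from GENCODE. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.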

Results

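Polyadenylated RNA was sequenced from primary mouse hepatic stellate cells, the vitamin A-storing pericytes of the liver sinusoid that can become matrix-producing myofibroblasts. The cells came from female C57BL/6JBomTac mice. On day 2 of culture they received 10 µM obeticholic acid (OCA), a semisynthetic bile acid that activates the nuclear receptor FXR, or the same volume of its vehicle DMSO (1:1000). After 3 h, 500 nM vasoactive intestinal peptide (VIP), a neuropeptide whose receptors raise cAMP, was added for 3 h more. Each group, DMSO+VIP and OCA+VIP, held 3 libraries. VIP was present in all 6 samples, so the effect of VIP itself was not analysed here and the comparison is of OCA against vehicle in cells then exposed to VIP. The labels do not state that the libraries of a group came from separate animals or cultures, so the p-values measure the spread between these samples, which may be technical.

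The deposited counts summed to 4.57e+06, 2.84e+06 and 3.73e+06 in DMSO+VIP libraries 1 to 3 and to 4.53e+06, 9.95e+06 and 5.80e+06 in OCA+VIP libraries 1 to 3. Low counts piled up at multiples of 3 and above all of 6. Of the counts above 0 and up to 30, 87.5%, 83.6% and 82.9% in the DMSO+VIP libraries lay within 0.5 of a multiple of 3, as did 84.4%, 65.4% and 84.6% in the OCA+VIP libraries, where an even spread gives 50%. If each sampled fragment stands for 6 counts, as the spacing of the low counts would give, the depth is 4.73e+05 to 1.66e+06 fragments per library; the cause of the steps is not known. OCA+VIP library 2 was both the deepest and the least stepped. Across the tested genes, log2 CPM (counts scaled to the normalised library size) correlated at 0.922 to 0.969 within groups and at 0.895 to 0.943 between groups. The first principal component held 40.1% of the variance and had negative values in the 3 DMSO+VIP libraries and positive values in the 3 OCA+VIP libraries. On the second, with 23.7% of the variance, DMSO+VIP library 2 lay at -47.0 and DMSO+VIP libraries 1 and 3 at 23.8 and 36.7. The ribosomal RNA gene Rn45s took 0.546% of counts in OCA+VIP library 1 and 0.194% to 0.287% in the other libraries.

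**Figure D1:**
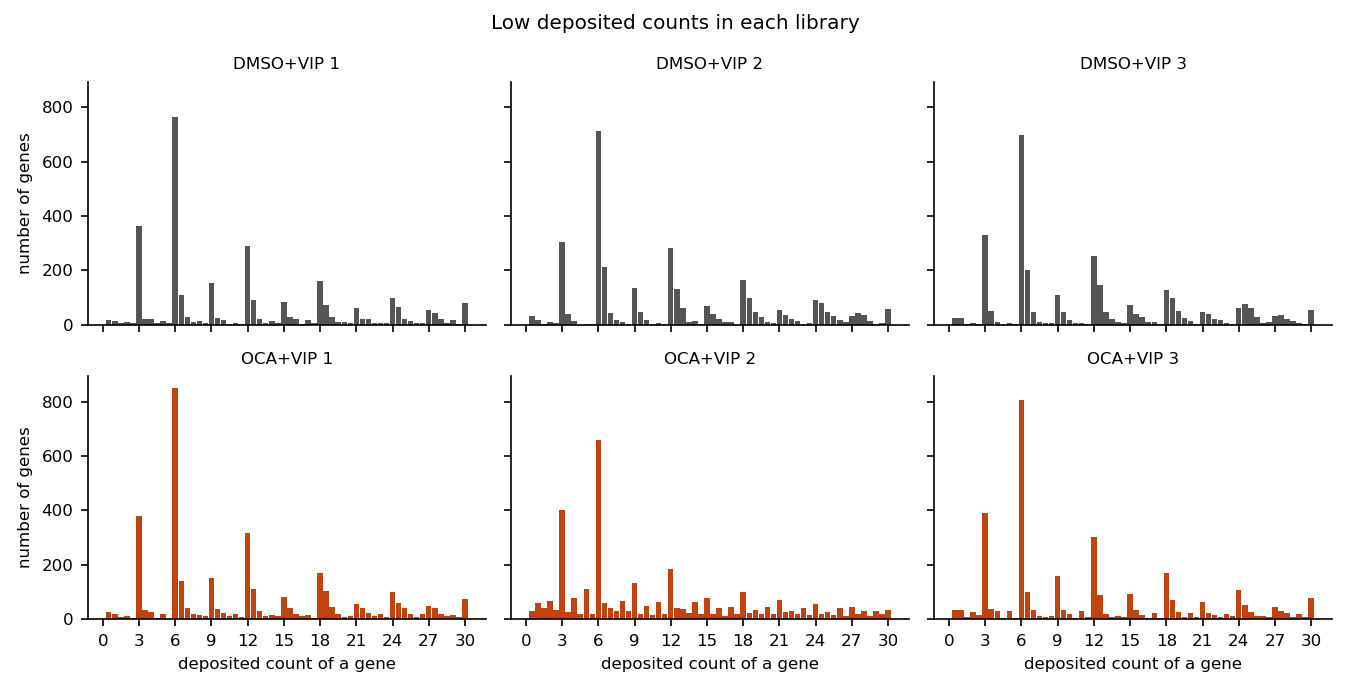
Number of genes (vertical axis) at each deposited count from 0.5 to 30 (horizontal axis), in 1 panel per library, with DMSO+VIP in grey and OCA+VIP in orange. The bars stand highest at 3 and 6 in each library, and OCA+VIP library 2 has the most genes between the multiples of 3 (112 genes at a count of 5, against 3 to 28 in the other libraries).

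With OCA before VIP, 19 of 37 genes of the extracellular matrix list, 12 of 24 of the cAMP-CREB list and 10 of 22 of the ATF4 and unfolded protein response list fell, while 0, 2 and 2 rose. Each of these 3 lists passed the set test with a preset correlation but not with an estimated one (adjusted p = 0.062 for each). RNA of the immediate early gene Egr1, the FXR target Osgin1 and 9 of 17 hepatocyte markers was higher (adjusted p = 0.30 for the markers with an estimated correlation). Of 19 contractile and SRF-YAP genes, 8 fell, among them Ankrd1, and 4 rose, among them Amotl2 and Cyr61 (camera adjusted p = 0.21). Of 11286 genes tested, 646 were higher and 682 lower with OCA, 1328 in all (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At least 2-fold differences were found for 127 higher and 242 lower genes. The count of changed genes was 877 without DMSO+VIP library 1, 737 without OCA+VIP library 1 and 751 without OCA+VIP library 3, and DESeq2 called 2245 genes. Of 93 named genes that passed the test, 26 did not pass when 1 of the libraries was left out, and those named here are given as such where they appear.

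Among the genes of the pathway under study, Vipr1 (chromosome 9, 121642716 to 121672954, mm10), which encodes the VIP receptor VPAC1, had 31.9 ± 6.00 CPM with DMSO+VIP and 52.1 ± 2.94 CPM with OCA+VIP (SD, n = 3). Its log2 fold change was 0.68 (SE 0.20, edgeR adjusted p = 0.027). This call was lost without any 1 of 5 libraries. The edgeR adjusted p of Vipr1 was 0.079 and 0.10 without DMSO+VIP library 2 or 3. It was 0.082, 0.061 and 0.076 without OCA+VIP library 1, 2 or 3. The log2 fold change of Vipr1 in these 5 fits was 0.59 to 0.70. Vipr2, encoding the receptor VPAC2, had a count of 0 in all 6 libraries. Nr1h4, which encodes FXR (chromosome 10, 89454234 to 89533622), had 15.04 ± 7.97 CPM with DMSO+VIP and 10.9 ± 3.06 CPM with OCA+VIP, a difference that did not pass the test (log2 fold change -0.48, SE 0.41, edgeR adjusted p = 0.50). Of 4 classical FXR targets, Slc51b had no counts, and Nr0b2, Slc51a and Abcb11 had 3, 3 and 14 counts, each in 1 OCA+VIP library. These lie under the floor of 18 counts per group, or 3 fragments of 6 counts, which corresponds to 1.61 CPM over the DMSO+VIP group and 0.887 CPM over the OCA+VIP group, so their regulation was not detectable at this depth.

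The genes of smallest p that rose with OCA were Amotl2, an angiomotin of the Hippo pathway, Egr1, Osgin1, Alb and Ccno. Amotl2 (chromosome 9, 102717804 to 102733417) went from 179 ± 38.2 to 609 ± 89.9 CPM (n = 3 each), a log2 fold change of 1.76 (SE 0.16, edgeR adjusted p = 3.3e-07). Egr1 (chromosome 18, 34861207 to 34864956) went from 94.0 ± 10.8 to 276 ± 47.0 CPM, and Osgin1 (chromosome 8, 119437162 to 119446256) from 154 ± 19.2 to 417 ± 48.5 CPM. Their log2 fold changes were 1.55 (SE 0.15) and 1.43 (SE 0.14), and that of Ccno was 1.84 (SE 0.19). The genes of smallest p that fell were Rcsd1, Inhba, Col5a2, Thbd and Prss23. Rcsd1, encoding a regulator of actin capping (chromosome 1, 165648945 to 165708094), went from 184 ± 3.88 to 26.6 ± 8.71 CPM and was 6.93-fold lower (edgeR adjusted p = 1.7e-09). Inhba, encoding the activin beta A subunit (chromosome 13, 16011851 to 16031609), was 3.30-fold lower, and Col5a2, a fibrillar collagen chain (chromosome 1, 45374331 to 45503282), was 3.79-fold lower, both with edgeR adjusted p = 9.7e-09. Thbd, encoding thrombomodulin, and Prss23, a serine protease, had log2 fold changes of -1.90 and -1.59. An antisense gene, Prss23os, shares 22.94% of the exon bases of Prss23, and the sources used here do not say whether counting used strand.

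**Figure D2:**
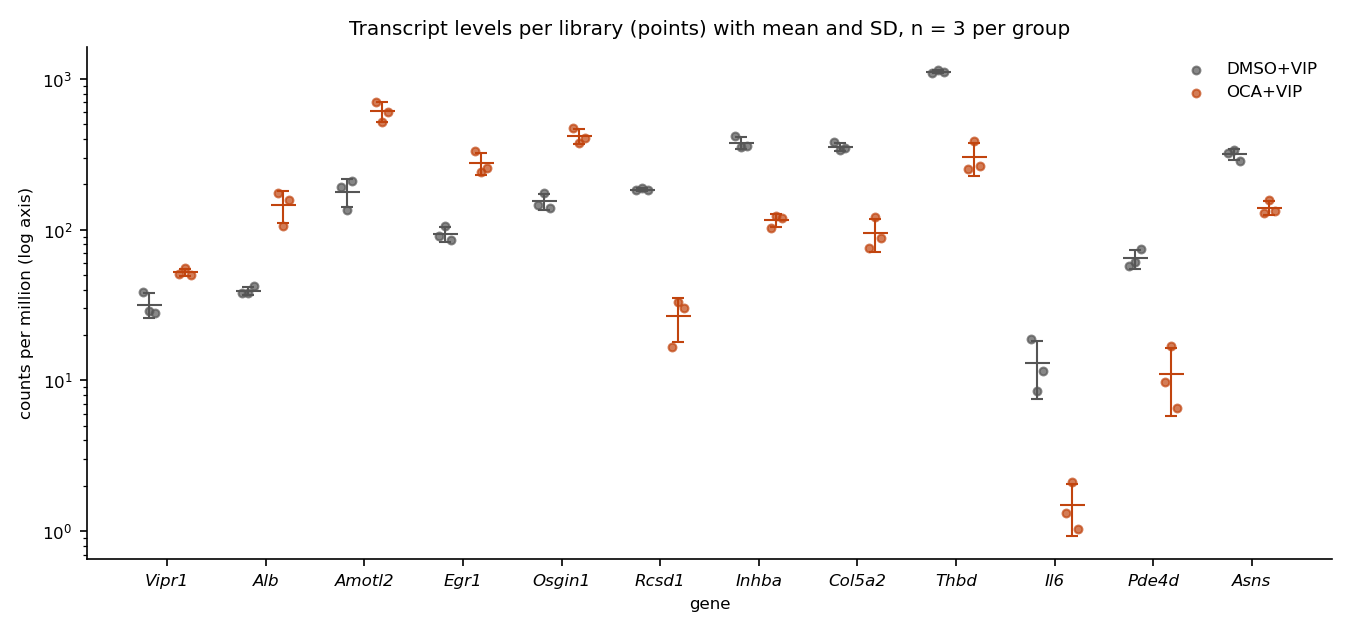
CPM (log axis) of 12 named genes (horizontal axis) in each library, as points, with the group mean and SD as bars, for DMSO+VIP (grey, n = 3) and OCA+VIP (orange, n = 3). Points of the groups do not overlap for any of the 12 genes, and Rcsd1 lies at 184 CPM on average with DMSO+VIP and at 26.6 CPM with OCA+VIP.

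The choice by fitted size of rise took 8 genes with a count of 0 in the 3 DMSO+VIP libraries, for which only a lower bound against the floor can be given, so their rank among the rises is not known. The plasma protein genes Ttr, Serpina1b and Apoh were at least 6.39-fold, 6.26-fold and 5.22-fold higher. Arhgap20 was at least 6.56-fold higher, the B cell receptor gene Cd79a at least 3.43-fold, the phospholipid transporter gene Abcb4 at least 2.53-fold, and the transporter genes Slc22a21 and Slc38a3 at least 2.41-fold and 1.79-fold. These bounds take the OCA+VIP count as measured. Abcb4, Slc22a21 and Slc38a3 had only 83, 79 and 58.5 counts over the OCA+VIP group, so with its counting error their folds could be smaller. Ces1c, a secreted carboxylesterase, and Sarm1 had 6 and 3 counts over the DMSO+VIP group, under the floor, so no fold is given. Ces1c had 0.437 ± 0.757 CPM with DMSO+VIP and 9.77 ± 1.66 CPM with OCA+VIP (edgeR adjusted p = 0.0035), and Sarm1 0.268 ± 0.464 and 4.81 ± 2.43 CPM (edgeR adjusted p = 0.031). Among the falls chosen by size, Gas7 and Cyb5r2 had 9 and 3 counts over the OCA+VIP group, also under the floor, against 9.02 ± 4.50 and 3.68 ± 0.510 CPM with DMSO+VIP. The other falls were those of Stox2 (-3.57), Chac1 (-3.39), Syt13 (-3.34), Fam129a (-3.33), Il6 (-3.09), Adra2b (-2.79), Rcsd1 (-2.79) and P2ry14 (-2.79, log2 fold changes). Il6, the cytokine interleukin 6, went from 13.0 ± 5.38 to 1.49 ± 0.558 CPM, and the receptor gene Adra2b from 46.0 ± 5.61 to 6.54 ± 2.76 CPM. Calls were lost on leaving out a single library for Abcb4 and Slc22a21 (OCA+VIP library 1, adjusted p = 0.068 and 0.053) and for Gas7 (DMSO+VIP library 1, adjusted p = 0.057). They were also lost for Syt13 (3 libraries, adjusted p from 0.053 to 0.20), Slc38a3 (4 libraries, 0.063 to 0.12), Sarm1 (5 libraries, 0.071 to 0.18) and Cyb5r2 (any of the 6 libraries, 0.052 to 0.17), all by edgeR.

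Of 37 measured members of the list of extracellular matrix and crosslinking genes, 19 fell, 0 rose and 18 did not pass the test (2 higher and 22 lower adjusted over the list alone), with a median log2 fold change of -0.78; without OCA+VIP library 2, 18 fell and 2 rose. Col5a2, the matricellular gene Postn, the protease genes Adamts1 and Mmp14, and Col1a1, which encodes the main chain of type I collagen, were among them, with log2 fold changes of -1.92, -1.55, -1.25, -1.43 and -1.79. Col1a2 and Col3a1, which encode chains of the same fibrils, did not pass the test (-0.34 and 1.49). Col1a1, Col1a2 and Col3a1 were chosen after their values were seen. The list stood apart from the other tested genes by camera with a preset correlation of 0.01 (adjusted p = 6.1e-17), but not with the correlation estimated from the data (adjusted p = 0.062). The sum of the list was 12459 ± 246 CPM with DMSO+VIP and 7623 ± 158 CPM with OCA+VIP (SD, n = 3). In the same libraries the sum of hepatocyte markers was 204 ± 15.2 and 457 ± 99.8 CPM.

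Of 24 measured genes that cAMP and its transcription factor CREB induce in many cell types, 12 fell, 2 rose and 10 did not pass the test (14 lower and 2 higher adjusted over the list alone), with a median log2 fold change of -0.42. The phosphodiesterase gene Pde4d went from 64.4 ± 9.37 to 11.1 ± 5.29 CPM, a log2 fold change of -2.54 (SE 0.27, edgeR adjusted p = 1.5e-06). Crem, a CREB family member, and Gem, a small GTPase, had log2 fold changes of -1.04 and -0.96, and the AP-1 genes Fosb and Fos of 1.24 and 0.92. The camera adjusted p was 1.1e-06, and 0.062 with an estimated correlation. Fos was chosen after its values were seen. The count of lower members was 7 without DMSO+VIP library 1, DMSO+VIP library 2 or OCA+VIP library 3. Of 21 genes for VIP receptors and the Gs-cAMP pathway, Vipr1 rose and Akap12, Prkar2b and Adcy3 fell, and 17 did not pass the test (2 higher and 3 lower adjusted over the list alone), with a median of -0.07 and a camera adjusted p of 0.42. Akap12, a scaffold for protein kinase A, had a log2 fold change of -1.07. That of Adcy3, whose exons overlap Cenpo on the opposite strand over 22.09% of their bases, was also -1.07, and its call was lost on leaving out any 1 of 3 libraries (edgeR adjusted p from 0.060 to 0.16).

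In the list of G protein-coupled receptors of stellate cells, 5 of 15 measured members fell and 10 did not pass the test (7 lower adjusted over the list alone), with a median log2 fold change of -0.37. The endothelin receptor genes Ednrb and Ednra had log2 fold changes of -1.27 and -1.72. Those of the prostaglandin receptor gene Ptger2, the nucleotide sugar receptor gene P2ry14 and the sphingosine 1-phosphate receptor gene S1pr1 were -1.71, -2.79 and -1.95, the last chosen after its values were seen. By camera the adjusted p of the receptor list was 7.4e-05, and 0.15 with an estimated correlation. Inflammatory NF-kB genes included 7 that fell, 1 that rose and 13 that did not pass the test among 21 (7 lower and 1 higher adjusted over the list alone), with a median of -0.26. Il6, Il11, the alarmin gene Il33 and the chemokine gene Ccl7 were lower, with log2 fold changes of -3.09, -2.50, -1.93 and -1.12, while the chemokine gene Cxcl10 rose (1.03) and was chosen after its values were seen. Without OCA+VIP library 1 or OCA+VIP library 3, 0 genes of the list rose, and without OCA+VIP library 2, 2 did. For this list the camera adjusted p was 0.0020, and 0.11 with an estimated correlation.

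Of 22 measured genes of the ATF4-CHOP and unfolded protein response list, 10 fell, 2 rose and 10 did not pass the test (11 lower and 2 higher adjusted over the list alone), with a median log2 fold change of -0.29. Among the members of smallest p, Asns, asparagine synthetase, went from 315 ± 26.5 to 140 ± 15.7 CPM (log2 fold change -1.19, SE 0.12, edgeR adjusted p = 1.4e-06), and Mthfd2 and Phgdh, enzymes of one-carbon and serine metabolism, and the pseudokinase gene Trib3 had log2 fold changes of -1.37, -1.79 and -1.63. The members that rose were Sesn2 (0.58) and the chaperone gene Dnajb9 (0.54), which were chosen after their values were seen; 1 member rose without DMSO+VIP library 1, DMSO+VIP library 2, OCA+VIP library 1 or OCA+VIP library 3. The camera adjusted p was 4.4e-06, and 0.062 with an estimated correlation. Of 16 p53 targets, 3 fell (Gdf15, Bbc3 and Ccng1), Plk2 rose and 12 did not pass the test (7 lower and 1 higher adjusted over the list alone). Their median was -0.28, with a camera adjusted p of 0.0019 and an adjusted p of 0.30 with an estimated correlation. The number of lower p53 targets was 1 without DMSO+VIP library 2, DMSO+VIP library 3 or OCA+VIP library 1. Bbc3 and Ccng1 lost their calls without any 1 of 4 and 5 of the libraries (edgeR adjusted p up to 0.13 and 0.16), and Plk2 without DMSO+VIP library 1 (0.051).

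Among hepatocyte markers, 9 of 17 measured members rose, 1 fell and 7 did not pass the test (14 higher and 1 lower adjusted over the list alone). The median log2 fold change was 2.23, also with the 2 members at 0 in the vehicle group set at their bound. Alb, serum albumin (chromosome 5, 90460870 to 90476602), went from 39.5 ± 2.35 to 146 ± 35.7 CPM (log2 fold change 1.88, SE 0.19, edgeR adjusted p = 9.2e-07). Ahsg, Apoa1 and Trf had log2 fold changes of 3.08, 2.37 and 1.64; a readthrough gene, Gm20425, shares 63.49% of the exon bases of Trf. Ass1, a urea cycle enzyme and the member that fell, had a log2 fold change of -0.78 and was chosen after its values were seen. The camera adjusted p was 4.4e-06, and 0.30 with an estimated correlation, and after thinning the libraries to an equal total of counts divided by 6, with 3 members left to test and 2 called higher, it was 0.077. Of 11 measured genes of the list of FXR-induced targets, Osgin1, C3, Abcb4 and Fgb rose, Ddah1 (chosen after its values were seen) fell (-0.93) and 6 did not pass the test (6 higher and 1 lower adjusted over the list alone). The median log2 fold change was 1.64, and 1.43 with Abcb4 at its bound. C3, complement component 3, and Fgb, fibrinogen beta, are abundant hepatocyte products, and Fgb is a member of both lists. The camera adjusted p was 0.0017, 0.11 with an estimated correlation and 0.38 after thinning. In this list 2 members rose without OCA+VIP library 1, Ddah1 was not called without any 1 of 5 libraries (all but OCA+VIP library 2), and Fgb was not called without OCA+VIP library 1 (edgeR adjusted p = 0.28) or without DMSO+VIP library 1 (0.079).

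**Figure D3:**
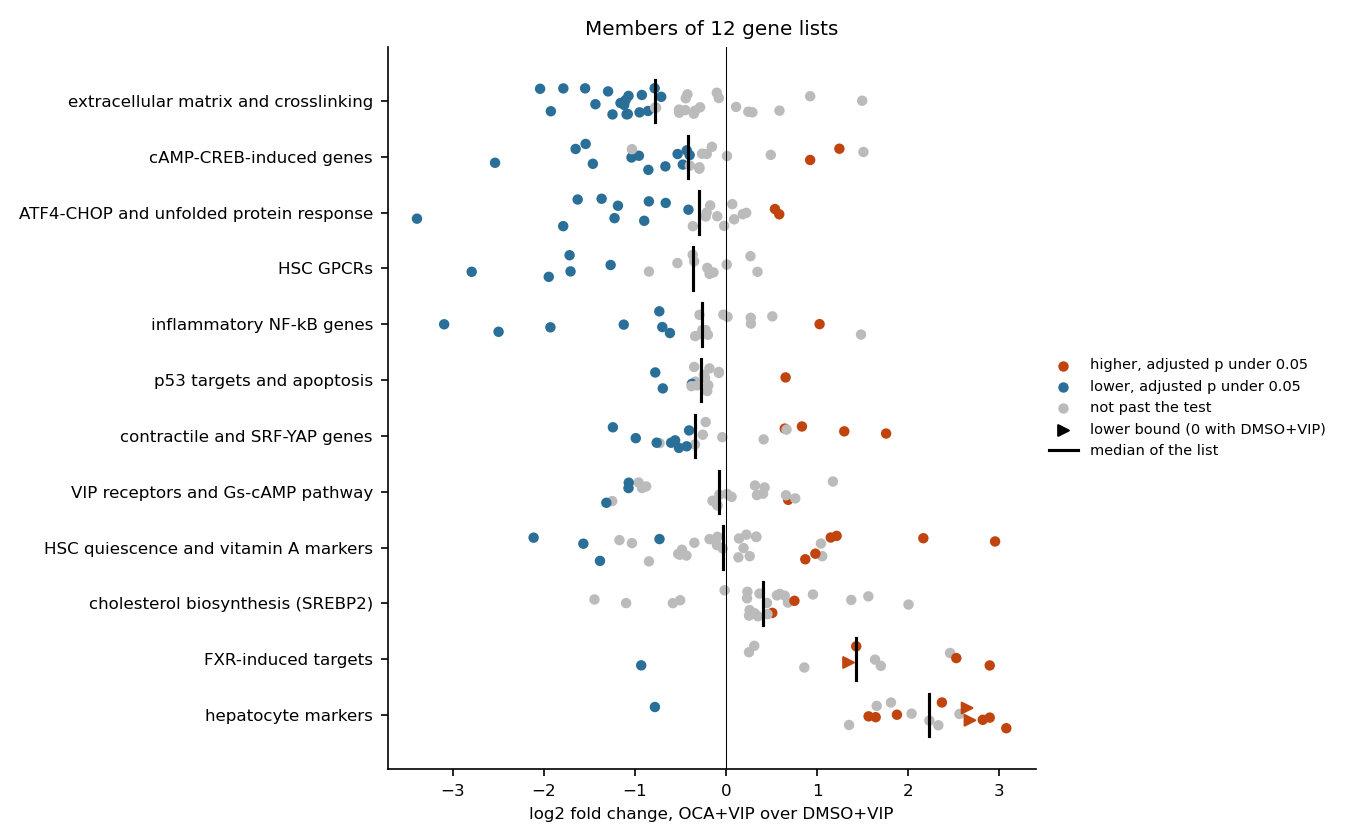
Log2 fold change of OCA+VIP over DMSO+VIP (horizontal axis) for each measured member of 12 gene lists (vertical axis, points spread for legibility), coloured by the edgeR call, with triangles at the lower bound for members at 0 in the DMSO+VIP libraries and a black line at the list's median. The median is -0.78 for the matrix list, -0.42 for the cAMP-CREB list and 2.23 for the hepatocyte list.

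Contractile and SRF-YAP genes moved both ways. Of 19 measured members, 8 fell, 4 rose and 7 did not pass the test (8 lower and 5 higher adjusted over the list alone), with a median log2 fold change of -0.34 and a camera adjusted p of 0.21. The myofibroblast marker Acta2, smooth muscle actin, went from 53.3 ± 7.75 to 22.8 ± 11.9 CPM (log2 fold change -1.24, SE 0.27, edgeR adjusted p = 0.0041), and Ankrd1 had a log2 fold change of -0.99. Amotl2, Cyr61, Lats2 and Vcl, vinculin, rose (1.76, 1.30, 0.83 and 0.64). Acta2 and Vcl were chosen after their values were seen. Gm49361, a protein-coding model on the same strand, shares 42.39% of the exon bases of Lats2. The number of lower members was 4 without DMSO+VIP library 1, and 5 without DMSO+VIP library 2, DMSO+VIP library 3 or OCA+VIP library 3. Markers of quiescent, vitamin A-storing stellate cells also split, with 6 higher, 4 lower and 21 that did not pass the test among 31 (6 higher and 6 lower adjusted over the list alone). Their median was -0.04, their mean 0.05 and the camera direction downward (adjusted p = 0.61). Cxcl12, Hgf, Bmp5 and Bmp10 fell (-1.38, -2.11, -1.57 and -0.73), while the matrix proteoglycan gene Dcn and the collectin gene Colec11 rose (0.98 and 2.17), as did Colec10, which had 12 counts over the DMSO+VIP group, under the floor, and 8.19 ± 3.999 CPM with OCA+VIP. Bmp10, Colec10 and Colec11 were chosen after their values were seen. The antisense gene Gm26903 shares 46.66% of the exon bases of Bmp5. The sum of the list was 4178 ± 207 CPM with DMSO+VIP and 3353 ± 38.5 CPM with OCA+VIP (SD, n = 3). Cxcl12 alone went from 1508 to 586 CPM, a larger fall than that of the sum.

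Of 24 measured cholesterol biosynthesis genes, 2 rose and 22 did not pass the test (4 higher and 1 lower adjusted over the list alone), and 1 rose without DMSO+VIP library 3, OCA+VIP library 1 or OCA+VIP library 3. Their median log2 fold change was 0.41, and Insig1, which restrains sterol synthesis, rose (0.75). The camera adjusted p was 0.018, 0.25 with an estimated correlation and 0.084 without OCA+VIP library 2. Of 22 TGF-beta and PDGF signalling genes, Inhba (-1.72) and Smad6 (-0.87) fell and Tgfbi (1.21) and Pdgfra (0.71) rose, with 4 lower and 3 higher adjusted over the list alone, a median of -0.0049 and a camera adjusted p of 0.61. The number of lower members was 4 without DMSO+VIP library 3 and 1 without DMSO+VIP library 2 or OCA+VIP library 3. Smad6 and Pdgfra lost their calls without any 1 of 2 and 3 libraries (edgeR adjusted p up to 0.11 and 0.15). Of the 26 lists of at least 2 measured genes, 9 passed camera with the preset correlation, 0 with an estimated correlation and 12 by fry, which asks whether a list's genes move on balance in 1 direction. Splits of the libraries that mixed the 2 groups also passed 1 to 12 lists by camera with the preset correlation.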

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

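Counts divided by 6, thinning of these to equal totals and cyclic loess were chosen after the data were seen. The number of changed genes, 1328, lay between 1062 and 1706 under the other scalings, filters, tests, blocks and added settings, except DESeq2 with 2245 genes, 589 of them at least 2-fold. An adjusted p under 0.01 left 648 genes, fewer by construction, and one under 0.1 gave 1932. Leaving out libraries gave 433 to 1478 changed genes, 196 to 502 at least 2-fold, 79 to 136 list genes and 9 to 11 lists, with fewer samples in each fit. The fewest changed genes came without replicate 1 of both groups. Camera with an estimated correlation called 0 lists (9 with the preset correlation, 12 by fry). Preset camera called 11 lists without a filter and with counts divided by 6; interferon and proliferation genes passed without a filter (adjusted p = 0.031 for each), and retinoic acid genes and portal fibroblast and smooth muscle markers passed with counts divided by 6 (0.019 and 0.0051). The cause of the DESeq2 difference was not tested. The estimated correlation was above the preset 0.01 for matrix (0.085), receptor (0.082), cholesterol (0.021), p53 (0.20) and hepatocyte genes (0.42). It was under 0.01 for cAMP-CREB (0.0011), ATF4 (0.0032), FXR-induced (-0.063) and NF-kB genes (-0.013). For these lists a correlation higher than the preset is not why the call was lost. The unadjusted camera p of the cAMP-CREB list went from 8.3e-08 with the preset correlation to 0.0042 with the lower estimated one. Camera with an estimated correlation also uses the residual degrees of freedom, 4 here, which the preset form does not. A call lost in this way therefore does not by itself show that the genes of a list move together. How much this weighed in each list was not tested. With the replicate number as a block, edgeR called 1118 genes and 1096 of them were among the 1328. Deviations of libraries of the same number correlated at -0.04, -0.05 and 0.03 across genes, which are not independent replicates, so the numbers are not treated as pairs.

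Of 93 called named genes, 55 kept their call in every setting that gave a value and 0 reversed. The log2 fold change of Vipr1 ranged from 0.50 to 0.84 and lost its call in 9 of 21 settings, with adjusted p up to 0.26. Reversals were seen in 3 uncalled genes, and their cause was not tested. The log2 fold change of Csf1r was -1.04, but 0.043 with limma-voom and 0.43 without DMSO+VIP library 3, and ranged from -2.06 to 0.61 on leaving out libraries. The log2 fold change of Cd14 was 0.19, but -0.35 without DMSO+VIP library 2 and -0.065 without OCA+VIP library 2, and ranged from -0.61 to 1.47. The log2 fold change of Sox9 was 0.52 and ranged from -0.070, without replicate 3, to 1.01. Thinning left 7579 genes to test, and genes under 18 counts per group are beyond this depth.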

Other observations

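Among metabolic and stress lists, Mylip (log2 fold change 1.29), Me1 (0.74) and Fasn (0.58) rose and the cholesterol exporter gene Abca1 fell (-1.36) of 16 LXR and lipogenesis genes (median 0.09, camera adjusted p = 0.21). Pdk4 (1.34) and Angptl4 (1.70) rose and Acot2 (-0.76) fell of 17 PPAR genes (median 0.15, adjusted p = 0.23). Adm (1.31) and Hk1 (0.53) rose and Hk2 (-0.92) fell of 18 glycolysis and hypoxia genes (median 0.18, adjusted p = 0.14, 0.49 with an estimated correlation, and 0.0090 without OCA+VIP library 2). The replication genes Mcm7 (0.97) and Mcm3 (0.89) rose of 19 proliferation genes (median 0.31, adjusted p = 0.087, 0.30 with an estimated correlation, 0.042 without OCA+VIP library 2 and 0.031 without a filter). G6pdx (0.50) rose of 20 NRF2 genes (median 0.09, adjusted p = 0.58), with 1 higher and 3 lower without OCA+VIP library 1, and 3 higher and 1 lower without OCA+VIP library 2. Hoxa5 (-1.38) fell of 10 retinoic acid genes (median -0.42, adjusted p = 0.064, and 0.26 with an estimated correlation), a list past camera with the preset correlation without DMSO+VIP library 1 (0.029), DMSO+VIP library 3 (0.038), OCA+VIP library 1 (0.022) or OCA+VIP library 3 (0.029). Bst2 (-0.62) and Isg15 (-0.55) fell of 16 interferon genes (median -0.48, adjusted p = 0.20, 0.32 with an estimated correlation and 0.031 without a filter). Apoa1 (2.37) rose of 2 FXR-repressed genes (median 0.90, adjusted p = 0.72), and B2m (-0.68) fell and Polr2a (0.42) rose of 15 housekeeping genes (median -0.11, adjusted p = 0.43).

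Calls that were lost on leaving out single libraries in these lists were those of Isg15 and Hk1 (5 libraries each, edgeR adjusted p up to 0.17 and 0.099), Polr2a (5 libraries, up to 0.15), Angptl4 and Acot2 (4 libraries each, up to 0.13 and 0.11), G6pdx (DMSO+VIP library 2, 0.071), B2m (DMSO+VIP library 2, 0.056) and Hk2 (OCA+VIP library 3, 0.050). Macrophage markers summed to 35.8 ± 21.5 CPM with DMSO+VIP and 47.5 ± 7.84 CPM with OCA+VIP, with 0 of 3 tested genes called (median 0.19, mean -0.10, camera upward, adjusted p = 0.45). Of 7 endothelial markers Egfl7 fell (-1.25, lost without any 1 of 4 libraries, adjusted p up to 0.074), with a median of 0.46, a mean of 0.33 and camera downward (adjusted p = 0.73), and the sum was 574 ± 40.1 and 491 ± 18.2 CPM. Of 3 portal fibroblast and smooth muscle markers Fbln2 (-2.04) and Des (-0.52, lost without any 1 of 3 libraries, adjusted p up to 0.10) fell (adjusted p = 0.064), and the sum was 198 ± 20.4 and 131 ± 6.84 CPM. Of 2 cholangiocyte and mesothelial markers 0 were called (median 0.68, adjusted p = 0.42), and Cd79a was the 1 lymphocyte marker tested.

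Of the tests that follow, those of a lower stellate cell share, of the slope on depth and of FXR targets in the cells were chosen after the result was seen, as were the thinned and loess settings. Of the 10 splits of the 6 libraries into 3 and 3, only the real split (1) gave 1328 changed genes or 369 changed at least 2-fold. The other 9 gave 0 of either by edgeR, with 129 to 489 genes at an unadjusted p under 0.05 against 2930. For gene lists past camera with the preset correlation the real split gave 9 and the other 9 gave 1 to 12. The highest was that of DMSO+VIP libraries 1 and 2 with OCA+VIP library 1, so 2 splits reached 9. Each other split thus passed at least 1 list with 0 genes called, so a pass by preset camera does not by itself tell the groups apart. With 10 splits a share under 0.05 cannot be reached.

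Of 37 matrix genes, 19 fell with OCA, and the list's call is lost with an estimated correlation (adjusted p = 0.062). Genes above 10 log2 CPM lay -0.41 below the average in OCA+VIP library 2, so compression of abundant genes was tested: after cyclic loess the matrix median was -0.68, which argues against it as the whole cause. For a lower share of stellate cell RNA to account for the fall of the summed list, other cells would have to replace 38.8% of it, but all markers of 6 other cell types together held 0.115% of counts with OCA, Alb among them at 146 CPM, which argues against it as the whole cause. Stellate markers went both ways (median 0.74 above that of the matrix list, SD 1.07, permutation p = 0.0025). Their sum fell from 4178 to 3353 CPM, but the marker Cxcl12 alone fell by more, from 1508 to 586 CPM. The sum therefore does not show a loss of share, and a smaller loss of share stays open. A response of the cells to OCA, direct or through other cells, stays open as a hypothesis from the same libraries.

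Of 24 cAMP-CREB genes, 12 fell and 2 rose with OCA, and the list's call is lost with an estimated correlation (adjusted p = 0.062). After cyclic loess their median was -0.43, which argues against compression of abundant genes as the whole cause. A lower stellate share would need other cells to replace 23.0% of stellate RNA, against the same 0.115% of counts in markers of other cell types, which argues against it as the whole cause. The stellate marker median lay 0.38 above that of this list (permutation p = 0.074). The summed markers fell from 4178 to 3353 CPM and the summed list from 6337 to 4881 CPM. The marker Cxcl12 alone fell from 1508 to 586 CPM, more than the whole marker sum, so that sum does not show a loss of share. A smaller loss of share stays open. Every library received VIP, so whether OCA changed the response to VIP or the level without VIP was not tested.

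Of 17 hepatocyte markers, 9 rose and 1 fell with OCA, and the list's call is lost with an estimated correlation (adjusted p = 0.30). A second list, written before its values were seen, had a median log2 fold change of 2.09, with 6 of 6 tested genes positive and 0 called. Members near 0 with vehicle could enter the test only if they were high with OCA, which favours positive values among the tested genes. The sum over all members of this second list, tested or not, was 22.7 CPM with DMSO+VIP and 75.4 CPM with OCA+VIP, so RNA from hepatocytes in the OCA+VIP libraries may contribute. Of the fixed list, 8 of 17 tested genes had at least 1 CPM in each DMSO+VIP library, 2 belong to another list, and Alb had 39.5 and 146 CPM. Greater depth is argued against: within groups the log2 of the list's summed CPM fell with the log2 total (slope -0.50, SE 0.078), where the difference between groups would need a slope of 1.41. The total is also the denominator of CPM, so this slope means that the list's counts rose less than the total, for a reason that was not tested. The median after thinning (1.69 over 3 tested genes) decides nothing, since thinning keeps the expected share. Whether the cells switched on FXR targets themselves cannot be told apart from added RNA, since 0 of the 4 classical targets were above the floor.

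ERK signalling was a hypothesis raised by higher Egr1, Fos, Hbegf (2.47 to 38.5 CPM) and Dusp6 (log2 fold change 1.41), the last 3 chosen after their values were seen. Of 18 other tested ERK feedback and immediate early genes, 13 were positive, with a median of 0.40 (camera p = 8.0e-04, and 0.067 with an estimated correlation). Fosl1 (0.54) and Ereg (1.03) passed the test, both chosen after their values were seen. Over all genes 1328 of 11286 passed, so 2 of 18 is no larger a share. Higher ERK-driven transcription after OCA stays a hypothesis, since the estimated correlation does not pass. A second hypothesis was lower ATF4-driven transcription. Of 20 other tested amino acid transport and tRNA ligase genes, 11 fell, 0 rose and 2 were positive, with a median of -0.41. Their camera p was 7.5e-11, and 0.0061 with an estimated correlation, neither adjusted over lists. The direction is that of the hypothesis. With an estimated correlation the fixed ATF4 list also had an unadjusted camera p of 0.0061 (0.062 adjusted), so by that form the second list did not pass more strongly than the first. With the preset correlation the unadjusted camera p of the fixed list was 6.8e-07, larger than that of the second list. Splits that mixed the groups also passed lists by the preset form.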
